A study of Mus musculus with 52 samples.

How the data were processed

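RNA was sequenced from the kidney medulla and the heart atria of mice that were all labelled as lacking the low-density lipoprotein receptor (Ldlr KO) and of which one set was labelled as also lacking Ipr, the receptor for prostacyclin (PGI2), encoded by Ptgir (labelled DKO). Per the labels' protocols, the mice were put on chow with 8% NaCl and drinking water with 0.9% NaCl for 2 weeks from 8 to 10 weeks of age, and libraries were made with a strand-preserving kit from poly(A)-selected RNA. Every one of the 52 libraries was placed in its group by its title. The labels number libraries as separate samples and do not say in words that each came from its own animal, so the p-values measure the spread between these samples.

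The deposited values are whole-number counts of reads per gene, in one table for each tissue, with no normalization. Per the submitters' processing notes, STAR 2.7.6a and the build GRCm38 were used, with no role stated for either. The counter, the gene annotation and the strand setting are not given in the sources used here, so counts of overlapping, antisense or near-identical genes are uncertain. The table coordinates lay 300 base pairs (kidney) or 200 base pairs (atria) beyond the GENCODE M21 gene at each end for 28155 of 28436 and 31170 of 31472 genes. Positions printed here are GENCODE M21 positions on GRCm38, and 28385 and 31414 identifiers were found there. Deposited counts summed to between 12747168 and 14171655 per kidney library and to between 22559645 and 22892005 per atrial library. Totals as close as those of the atria leave open that reads were drawn down to a common number before deposit.

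Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr by group, which left 15020 genes in kidney and 15725 in atria. Libraries were scaled by TMM, and a quasi-likelihood model with robust dispersions was fitted to the 16 kidney libraries and, separately, to the 36 atrial libraries with 1 coefficient for each of the 4 sex and genotype groups. The contrasts were labelled DKO against Ldlr KO in each tissue and sex, the interaction of sex with genotype in atria, and females against males within each genotype. P-values were adjusted by Benjamini-Hochberg over all genes tested and a gene was called at an adjusted p below 0.05. Standard errors were taken from the log2 fold change and the F statistic. Levels are given as CPM (each count over the library total of the genes kept times its TMM factor, scaled to the usual common total), as mean ± SD. No pair of libraries within a group agreed within sampling noise, since the smallest ratio of observed to Poisson variance was 2.42, and so all libraries were counted as separate.

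Lists of genes for pathways, cell types and RNA quality, 52 in all with a list of sex-linked genes used only to check labels, were fixed before the data were examined, as were the contrasts, the filter, the tests and most alternatives. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 37 kidney or 38 atrial lists, and again with an estimated correlation. Beside each count over all genes tested, a count adjusted over the list alone was made. The fry test was run as a further alternative.

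Genes are named by a rule: Ptgir and Ldlr, then for each contrast the 10 called genes with the smallest p in each direction and the 3 with the largest fold in each direction, with a mean of at least 1 CPM and an established symbol. The rule adds up to 4 members with the smallest p from each list described, always Nppa, Nppb, Npr1, Npr3 and Corin, and the 5 smallest p as values where fewer than 5 genes passed. Y-linked genes and Xist are given apart. Genes named outside the rule are said to have been chosen after their values were seen.

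The fits were tested on simulated counts drawn from the means, dispersions and library sizes of the real samples, with known changes put into a random set of genes. In the kidney comparison 62.7% of the genes changed 1.5-fold, 91.0% of those changed 2-fold and 98.5% of those changed 4-fold were called, among 14899 genes tested. The same shares were 95.5%, 100% and 100% for the female atria (15645 genes) and 94.0%, 100% and 100% for the male atria (15637 genes). For the interaction they were 85.1%, 95.5% and 100% (15637 genes). Females against males gave 91.0%, 100% and 100% in Ldlr KO (15638 genes) and 97.0%, 100% and 100% in labelled DKO (15633 genes). False calls made up 5.15%, 3.42%, 8.54%, 4.02%, 3.45% and 2.16% of the calls in these 6 comparisons, in that order. In these simulated counts, then, a change of 1.5-fold was missed more often in kidney than in atria. The dispersions used leave out the further spread of each gene that the quasi-likelihood test estimates, so genes that vary more are not represented. Each gene was drawn on its own in each library, so the simulated counts hold no structure shared between libraries. The random splits given further on point to such structure in the real counts, and the shares above may not carry over to them.

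The alternatives were RLE size factors, no filter, a filter of at least 1 CPM on average, DESeq2 1.42.0, limma-voom with quality weights, surrogate variables from sva 3.50.0, a fit of only the compared groups, the second index sequence as a kidney covariate, a block for adjacent label numbers in atria, and leaving out each library in turn. After the data were seen, offsets for transcript length and GC content, the kidney libraries of each second index alone, fits without genes within 20 Mb of Ptgir and fits without single atrial libraries that stood apart were added. Transcript length and GC content were taken from the longest annotated transcript of each gene. In kidney 12 libraries, 6 of each genotype, shared 1 second index and the remaining 2 of each genotype shared another. In atria each library had its own second index, so it marked no batch. Real contrasts were also compared with 100 random splits of the same libraries.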

Results

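The series measured gene expression by RNA sequencing in 52 libraries from mice on a high salt diet, on a background labelled as lacking Ldlr, the receptor that clears low-density lipoprotein from blood. The question named by the title is how blood pressure is kept in mice without the receptor for PGI2 (prostacyclin, a lipid that relaxes vessels), and whether the answer depends on sex. Kidney medulla from males gave 8 Ldlr KO libraries, with 13279792 to 14171655 counts each, and 8 labelled DKO libraries, with 12747168 to 13318217 counts each. Heart atria gave 9 libraries in each of 4 groups, female and male Ldlr KO and female and male labelled DKO, with 22559645 to 22892005 counts each. In every atrial library the Y-linked genes and Xist matched the labelled sex. Xist averaged 439 ± 115 CPM in female and 0.24 ± 0.14 CPM in male Ldlr KO atria (n = 9 each).

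Ptgir (ENSMUSG00000043017, chromosome 7, 16906490 to 16910905, plus strand), the gene of the targeted receptor, was higher rather than lower in libraries labelled DKO. In kidney it stood at 1.68 ± 0.66 CPM in Ldlr KO and 6.06 ± 0.56 CPM in labelled DKO (n = 8 each), a log2 difference of 1.84 (SE 0.198, adjusted p = 7.03e-05), and all 8 labelled DKO libraries exceeded the Ldlr KO mean. In male atria it stood at 6.99 ± 1.61 and 10.4 ± 1.79 CPM (n = 9 each), a log2 difference of 0.57 (SE 0.107, adjusted p = 0.00749). In female atria the levels were 9.15 ± 1.003 and 10.8 ± 1.08 CPM and the difference of 0.24 did not pass the test (adjusted p = 0.508). The transcript level thus goes against the DKO label, and every direction given here is from libraries labelled DKO relative to Ldlr KO. Counts per gene cannot show, for Ptgir or for Ldlr, whether a part of the gene was deleted or whether the transcript encodes a working receptor. Ldlr (ENSMUSG00000032193, chromosome 9, 21723483 to 21749919, plus strand), labelled as knocked out in all groups, was counted in all of them, at 33.4 ± 9.59 CPM in Ldlr KO and 47.9 ± 20.4 CPM in labelled DKO kidney (adjusted p = 0.124). In atria its difference did not pass the test in females (log2 difference 0.06, adjusted p = 0.863) or males (0.09, adjusted p = 0.999).

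**Figure D1:**
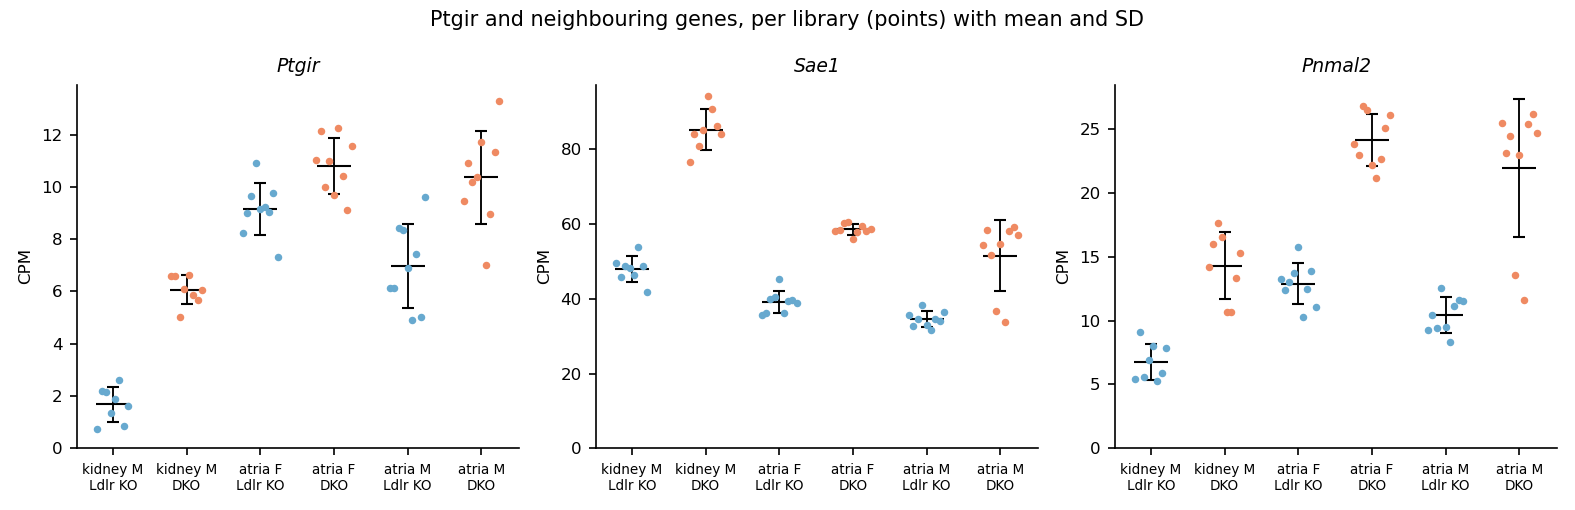
Levels of Ptgir and the neighbouring genes Sae1 and Pnmal2 in CPM (vertical axes, from 0) for each library (points) in the 6 groups (F, females; M, males), with the mean (long bar) and SD (error bars). Kidney Ptgir averaged 1.68 CPM in Ldlr KO and 6.06 CPM in labelled DKO, and 2 male labelled DKO atrial libraries, M10 and M18, had Sae1 levels of 36.7 and 33.8 CPM against 51.8 to 59.2 CPM in the other 7.

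In kidney medulla of males, 19 of 32 cytosolic ribosomal protein genes and 9 of 13 mitochondrial genome transcripts fell in labelled DKO against Ldlr KO, and 3 of 22 cholesterol synthesis genes and 3 of 7 smooth muscle and pericyte markers rose. When adjusted over the list alone these were 25, 9, 3 and 5. All 4 lists passed camera and none did so with an estimated correlation (adjusted p = 0.476, 0.47, 0.47 and 0.47 with an estimated correlation). The mitochondrially encoded oxidase subunit mt-Co2 fell from 2256 ± 425 to 1129 ± 277 CPM (n = 8 each; log2 change −0.998, SE 0.144, adjusted p = 0.00136), and the ribosomal protein gene Rps27 fell by 1.03 on the log2 scale (adjusted p = 0.00397). Slc6a6, the taurine transporter that medullary cells use against osmotic stress, rose from 217 ± 19.0 to 315 ± 44.2 CPM (log2 change 0.54, SE 0.0936, adjusted p = 0.00386). Ppara, a nuclear receptor that drives fatty acid oxidation, rose from 12.4 ± 2.34 to 20.6 ± 3.88 CPM (log2 change 0.73, SE 0.136, adjusted p = 0.00505). For each of these genes all 8 labelled DKO libraries lay on the same side of the Ldlr KO mean. In total 1433 of 15020 genes were called, 486 higher and 947 lower, and of the 135 that changed over 2-fold 16 were higher and 119 lower.

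Among the 32 cytosolic ribosomal protein genes 19 fell and none rose (25 fell when adjusted over the list alone), with a median log2 change of −0.58. Examples are Rps27, Rpl5 (−0.79), Rps23 (−0.84) and Rpl32 (−0.91). The median was −0.30 with surrogate variables (16 fell) and −0.35 with length and GC offsets (20 fell). Of the 13 mitochondrial genome transcripts 9 fell (9 when adjusted over the list alone; median −0.60), including mt-Co2, mt-Co3 (−1.002), mt-Nd3 (−0.90) and mt-Atp6 (−0.77), with a median of −0.30 with length and GC offsets (6 fell). Both groups were lower than other genes (camera adjusted p = 3.5e-15 and 8.38e-09; adjusted p = 0.476 and 0.47 with an estimated correlation). The share of all counts on the mitochondrial genome, also a measure of RNA quality and cell makeup, was 15.4 ± 2.35% in Ldlr KO and 11.3 ± 2.01% in labelled DKO kidney. Ribosomal protein genes have many processed copies and mitochondrial genes have nuclear copies, so these counts can hold shared reads. Of 33 nuclear genes of oxidative phosphorylation 7 fell (1 rose and 10 fell when adjusted over the list alone; camera adjusted p = 0.00408; adjusted p = 0.732 with an estimated correlation). They include Ndufa4 (−0.88), Ndufb9 (−0.66), Ndufb5 (−0.49) and Uqcrb (−0.45), while the list median of −0.23 turned to 0.02 with length and GC offsets and to 0.04 with surrogate variables. In contrast Cox15 (0.46), needed to make the heme of the same oxidase, rose. The fall was steeper for shorter transcripts in general. Across 12827 protein-coding genes the fold change and transcript length had a Spearman rho of 0.381 (across genes, which are not independent replicates), and 412 of the 947 lower calls were not protein coding.

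Of 22 cholesterol synthesis genes 3 rose (3 when adjusted over the list alone), namely Hmgcs1 (0.47), Lss (0.33) and Srebf2 (0.36), the last a transcription factor that switches the pathway on. The list median was 0.26, with all 22 positive (camera adjusted p = 0.00112; adjusted p = 0.47 with an estimated correlation). Smooth muscle and pericyte markers rose in 3 of 7 cases (5 when adjusted over the list alone; median 0.38), namely the contractile genes Cnn1 (0.87) and Acta2 (0.44) and the pericyte gene Rgs5 (0.38) (camera adjusted p = 0.00404; adjusted p = 0.47 with an estimated correlation). Of 25 genes of fatty acid oxidation only Ppara passed (6 when adjusted over the list alone; median 0.21; camera adjusted p = 0.00993; adjusted p = 0.476 with an estimated correlation), and Acad11, an acyl-CoA dehydrogenase outside the list, rose (0.43, adjusted p = 0.00656). Markers of endothelium gave 1 gene that rose of 9, the junction gene Cdh5 (0.57; 1 when adjusted over the list alone; camera adjusted p = 0.0247; adjusted p = 0.637 with an estimated correlation). Proximal tubule markers moved both ways: the glucose-producing enzymes G6pc (0.45) and Pck1 (0.65) rose and the androgen-induced Kap (−0.55) fell, among 18 measured (6 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.0398; adjusted p = 0.732 with an estimated correlation). The remaining lists past camera in kidney were urothelium (1 of 6 rose, 2 when adjusted over the list alone; adjusted p = 0.0422) and extracellular matrix (0 of 23 called in edgeR, 0 when adjusted over the list alone; adjusted p = 0.0354), both at adjusted p = 0.732 with an estimated correlation.

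**Figure D2:**
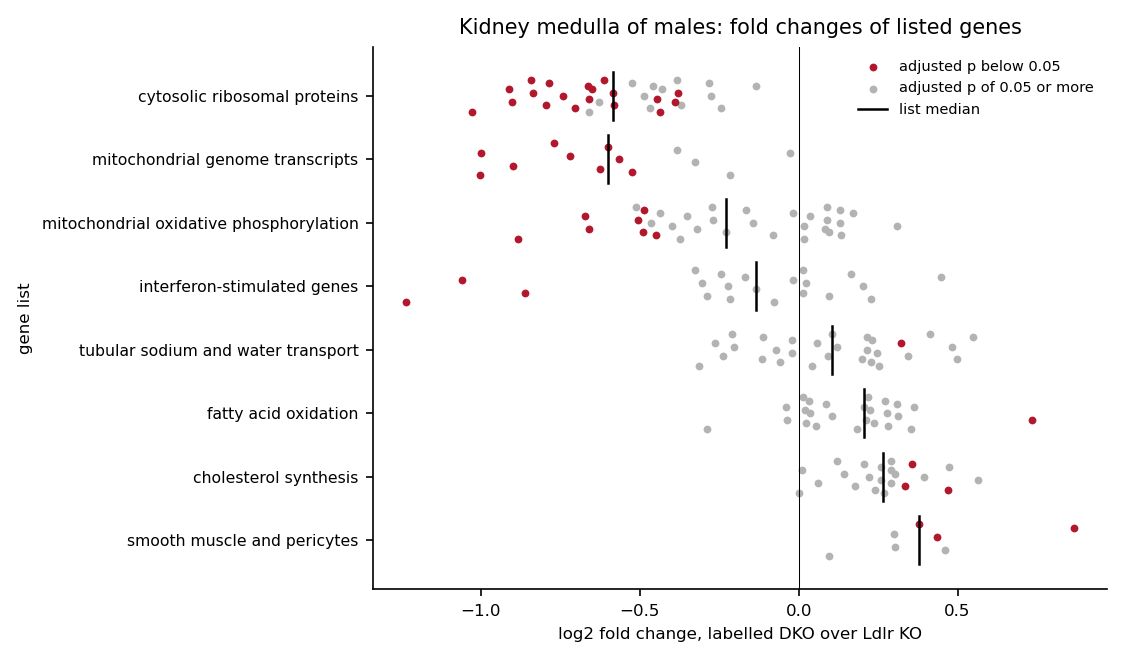
Log2 fold change of labelled DKO over Ldlr KO kidney medulla (horizontal axis) for each measured gene (points, spread vertically for sight) of 8 gene lists (rows); red points passed an adjusted p of 0.05 and black bars are list medians. All 32 ribosomal protein genes and all 13 mitochondrial genome transcripts lie below 0, and all 22 cholesterol synthesis genes lie above 0.

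Few genes of blood pressure control passed the test in kidney. Of 29 genes of tubular sodium and water transport Scnn1g, a subunit of the epithelial sodium channel, passed over all genes (0.32, adjusted p = 0.0405) and 0 passed when adjusted over the list alone (camera adjusted p = 0.272). Enpep (0.63, adjusted p = 0.0162), the aminopeptidase that degrades angiotensin II, rose as the 1 call among 14 genes of the renin-angiotensin system (1 when adjusted over the list alone; camera adjusted p = 0.0712). Pde5a (0.70, adjusted p = 0.0241), which degrades cGMP, rose as the 1 call among 13 genes of the natriuretic peptide pathway (1 when adjusted over the list alone; camera adjusted p = 0.183). By the fry test both lists passed as higher (adjusted p = 0.0307 and 0.0424). By camera they had adjusted p = 0.476 each with an estimated correlation. The natriuretic peptide receptors Npr1 (−0.19, adjusted p = 0.295) and Npr3 (0.28, adjusted p = 0.341) and the activating protease Corin (0.58, adjusted p = 0.282) did not pass. None of 17 prostanoid genes other than Ptgir, which the list leaves out, was called by edgeR (0 when adjusted over the list alone; camera adjusted p = 0.879), with the smallest p in Ptgds at a log2 difference of −0.35 (adjusted p = 0.259).

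The interferon-stimulated genes Mx1 (−1.23), Ifi27l2a (−1.06) and Oas2 (−0.86) fell, as did 3 of 21 in all (3 when adjusted over the list alone), while the list as a group did not pass (camera adjusted p = 0.125). Cd3d (−1.51) fell as 1 of 5 T cell markers and Lyz2 (−0.56) as 1 of 9 macrophage markers (1 each when adjusted over the list alone; camera adjusted p = 0.272 and 0.935), with other members of both lists positive, and the survival gene Bcl2a1b (−1.37) fell. The immunoglobulin genes Igkc (0.79) and Jchain (0.65) rose as 2 of 4 B and plasma cell markers (2 when adjusted over the list alone; camera adjusted p = 0.314), and the variable segments Igkv3-10 (2.54) and Ighv1-72 (2.12) had among the largest rises at levels below 3 CPM. The antioxidant enzymes Cat (0.41) and Txnrd1 (0.31) rose as 2 of 22 in their list and the steroid enzymes Hsd17b7 (0.67) and Hsd17b4 (0.31) as 2 of 9 (2 each when adjusted over the list alone; camera adjusted p = 0.324 and 0.125; fry adjusted p = 0.00689 for the steroid list). Of 6 podocyte genes Podxl (0.40) rose and Synpo (−0.34) fell (1 each way when adjusted over the list alone; camera adjusted p = 0.214). Atp6v1g3 (−0.54), a proton pump subunit, fell as 1 of 10 intercalated cell markers (1 when adjusted over the list alone; camera adjusted p = 0.427), and Egf (0.42) rose as 1 of 8 markers of the thick ascending limb (1 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.761).

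The kidney test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment on 8 against 8 libraries, and the number of calls depended strongly on which libraries were used. Within the 12 libraries that shared a second index (6 of each genotype) 19 genes were called, 4 higher and 15 lower, against 1433 in all 16. Within the other index (2 libraries of each genotype) 296 were called, 27 higher and 269 lower, of which 263 were among the 1433. The 19 include Ptgir, Sae1, Pnmal2, mt-Co2, mt-Co3, mt-Nd3, mt-Atp6, Mir99ahg and Ceacam2 and not the ribosomal, cholesterol or smooth muscle genes named above, and all 19 had the same sign in the 4 libraries of the other index, 18 of them at an unadjusted p under 0.05. In the 12 libraries the genes called in all 16 had a median of 0.876 times their fold change and 1.2 times their standard error. The 16 include the 12. Between the 12 and the 4 libraries the fold changes had a Pearson r of 0.655 over 14848 genes, which are not independent replicates. List medians in the 12 and in the 4 were −0.48 and −0.85 for ribosomal proteins, −0.51 and −0.94 for the mitochondrial genome, −0.19 and −0.37 for nuclear oxidative phosphorylation, 0.15 and 0.48 for cholesterol synthesis, 0.39 and 0.54 for smooth muscle and 0.15 and 0.33 for proximal tubule. Leaving out single libraries gave 813 (without ST5), 822 (ST15), 854 (ST6), 862 (ST4), 862 (ST7), 895 (ST10) and 2603 (ST12) calls. Surrogate variables gave 729, limma-voom 2254, and length and GC offsets 2228 with 47.7% higher in place of 33.9%. Calls that ended in at least 1 leave-one-out fit were those of Ndufb9 (without ST4), Txnrd1 (ST5 or ST15), Ndufb5 (ST4, ST7 or ST15), Pde5a, Oas2 and Igkc (4 of 16 fits each), Uqcrb, Acta2 and Kap (5), Cdh5 and G6pc (6), Ifi27l2a and Hsd17b4 (7), Pck1 (8), Scnn1g, Mx1 and Lyz2 (9), Lss, Jchain and Egf (10), Rgs5 (11), and Srebf2 and Synpo (12). The other genes named for kidney so far as called kept their call in all 16 fits.

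The 4 called kidney genes with the smallest adjusted p and an established symbol were Sae1, Ptgir, Pnmal2 and Ccdc84, and the first 3 lie together on chromosome 7. Sae1 (16320234 to 16387806, minus strand), a subunit of the enzyme that activates SUMO, rose from 48.0 ± 3.49 to 85.3 ± 5.48 CPM (n = 8 each; log2 change 0.83, SE 0.0691, adjusted p = 1.4e-06). Pnmal2 (16944682 to 16948828, plus strand) rose by 1.08 (SE 0.144, adjusted p = 0.000857). Ccdc84 (−0.68), the basal transcription factor subunit Gtf2a2 (−0.70), the antiviral gene Shfl (−0.77) and the noncoding Mir99ahg (−1.26) fell, and Pigg (0.72) and Tspan14 (0.38) rose, elsewhere in the genome. Within 20 Mb of Ptgir 49 of 363 tested genes were called, 13 higher and 36 lower, which is 13.5% against 9.44% of genes elsewhere (1-sided Fisher's exact p = 0.0081). Ceacam2 (chromosome 7), a cell adhesion gene with close relatives whose reads it can share, had the largest fall of the named genes, from 10.8 ± 9.18 to 0.60 ± 0.17 CPM (log2 change −4.14, adjusted p = 0.00406). Of the 8 Ldlr KO libraries ST4, ST5 and ST8 had 0.83, 0.38 and 0.22 CPM and the rest 10.6 to 21.1 CPM.

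In female atria, the genes that changed with the DKO label lay mostly around Ptgir. Pnmal2 rose from 12.9 ± 1.61 to 24.1 ± 2.05 CPM (n = 9 each; log2 change 0.91, SE 0.113, adjusted p = 8.24e-06), and Sae1 rose from 39.1 ± 2.95 to 58.7 ± 1.43 CPM (0.58, SE 0.0733, adjusted p = 8.24e-06). Trappc6a, of a vesicle tethering complex, rose by 1.08 and Gipr, the receptor for the gut hormone GIP, by 1.01. Ercc2, a helicase of DNA repair and transcription, fell from 21.5 ± 2.26 to 13.1 ± 0.23 CPM (−0.71, SE 0.0861, adjusted p = 8.24e-06). In total 38 of 15725 genes were called, 16 higher and 22 lower, and 30 of them lay within 20 Mb of Ptgir.

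Other neighbours of Ptgir that rose in female atria were Dhx34 (0.50), the muscle creatine kinase Ckm (0.38), Nectin2 (0.32), Bloc1s3 (0.36) and Napa (0.19). Those that fell were the exocyst gene Exoc3l2 (−0.90), Smg9 (−0.57), the glutamine transporter Slc1a5 (−0.58), Vasp (−0.50), the apolipoprotein gene Apoc1 (−1.24) and the complement receptor C5ar2 (−1.07). Gm45104, an unnamed locus in that region chosen after its values were seen, rose by 3.59. The calls near Ptgir spanned 3731630 to 24422778, and 7.58% of 396 genes tested there were called against 0.0522% elsewhere (1-sided Fisher's exact p = 1.46e-41). The 8 calls beyond were Mtr (0.27), the methionine synthase, Ppbp (−1.05), a platelet chemokine, Gmeb1 (−0.20) and, chosen after their values were seen, Milr1 (−0.81), Kif21b (−0.47), Rhno1 (−0.19), Gm11677 (3.24) and Gm5905 (−0.89). With the genes near Ptgir left out of the test 3 of these were called, Mtr, Gm11677 and Gm5905.

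None of the natriuretic peptide genes passed the test in female atria. Nppa, which encodes the main hormone of the atrium, stood at 25180 ± 2320 CPM in Ldlr KO and 25420 ± 667 CPM in labelled DKO (log2 difference 0.01, adjusted p = 0.944), and Nppb at 625 ± 248 and 493 ± 108 CPM (−0.34, adjusted p = 0.717). Corin (0.01, adjusted p = 0.979), Npr1 (−0.03, adjusted p = 0.862) and Npr3 (−0.15, adjusted p = 0.657) did not pass. No list had a member called over all genes in edgeR other than Ckm. The interferon-stimulated genes had a median of −0.22 and 0 of 21 called (camera adjusted p = 3.5e-08, and adjusted p = 0.762 with an estimated correlation). When adjusted over the list alone 8 were lower, among them Oas1a (−0.41), Ifit3 (−0.52), Mx2 (−0.56) and Stat1 (−0.28). Without F7 Ifit3 was at −0.27 and Mx2 at −0.32. Whichever library was left out, Oas1a stayed at −0.37 or below and Stat1 at −0.24 or below. Of 16 immediate early genes 0 were called over all genes (camera adjusted p = 0.0092, and adjusted p = 0.762 with an estimated correlation). When adjusted over the list alone 2 were lower, Fos (−1.73, and −1.02 without F9) and Egr1 (−1.12, and −0.74 without F9). Nuclear oxidative phosphorylation (median 0.05), heat shock and unfolded protein response (0.10) and fatty acid oxidation (0.04) were higher as groups, and erythroid (−0.53) and T cell (−0.35) markers lower, by camera alone (adjusted p = 5.76e-06, 0.00103, 0.0242, 0.00249 and 0.0177). Each of these 5 lists had an adjusted p = 0.762 with an estimated correlation.

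The female test was the edgeR contrast within the fit of 36 libraries. The calls of Nectin2 (without F11) and Vasp (without F4) ended in 1 leave-one-out fit each, and those of Rhno1, Napa, Kif21b, C5ar2, Bloc1s3, Apoc1 and Gmeb1 in 19, 15, 12, 11, 10, 9 and 6 of 36. Without F9 the changes of Gm45104 and Gm11677 reached 5.45 and 4.83.

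In male atria the same region led. Pnmal2 rose from 10.4 ± 1.40 to 21.9 ± 5.43 CPM (n = 9 each; log2 change 1.08, SE 0.115, adjusted p = 5.44e-07), Sae1 from 34.6 ± 2.07 to 51.6 ± 9.60 CPM (0.58, SE 0.0737, adjusted p = 1.87e-05) and Trappc6a and Gipr by 0.88 and 0.91. The zinc finger genes Zfp112 (0.50) and Zfp61 (0.49) and Dhx34 (0.45) rose, and Ercc2 (−0.50), Exoc3l2 (−0.71) and C5ar2 (−1.26) fell. Of the 17 genes called, 14 higher and 3 lower, 16 lay within 20 Mb of Ptgir (5059277 to 24301232), and the other was Gm11677 (3.69; chromosome 11, 111724648 to 111725624), chosen after its values were seen. That is 4.04% of the genes near Ptgir against 0.00652% elsewhere (1-sided Fisher's exact p = 3.22e-25).

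**Figure D3:**
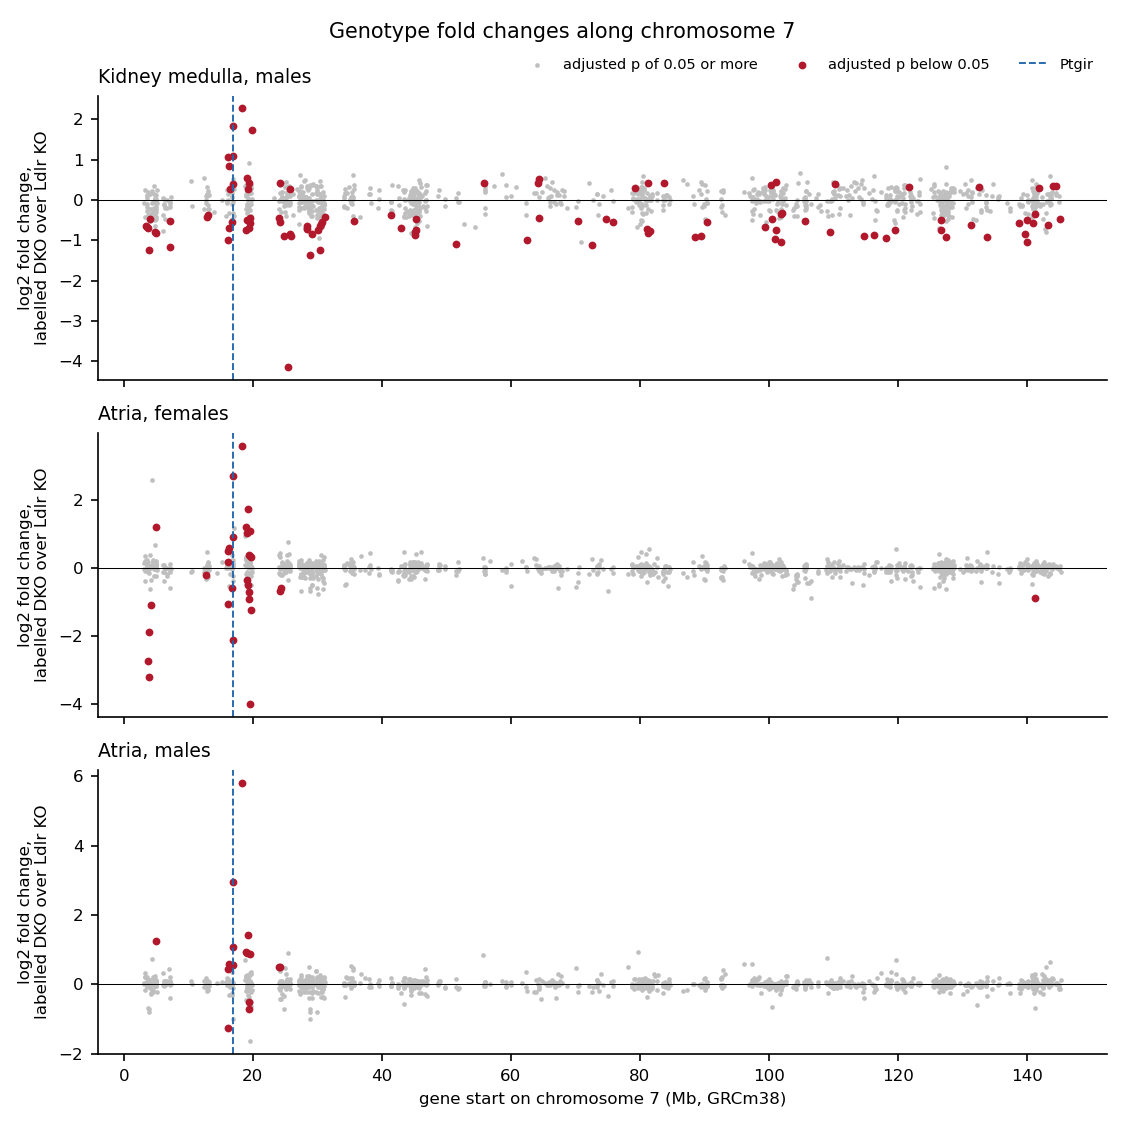
Log2 fold change of labelled DKO over Ldlr KO (vertical axes, which differ in range) against gene start on chromosome 7 in Mb (horizontal axis) for kidney, female atria and male atria; red points passed an adjusted p of 0.05 and the dashed line marks Ptgir. In atria 30 female and 16 male calls lie within 20 Mb of Ptgir and 1 female and 0 male calls lie on the rest of the chromosome, where the kidney had 60.

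None of the natriuretic genes passed in male atria either: Nppa stood at 23610 ± 2317 CPM in Ldlr KO and 24040 ± 1945 CPM in labelled DKO (log2 difference 0.03), Nppb at 516 ± 206 and 456 ± 244 CPM (−0.18), and Npr1 (−0.02), Npr3 (−0.14) and Corin (−0.01) likewise had adjusted p = 0.999. No list had a member called in edgeR over all genes. By camera alone extracellular matrix (median 0.12, adjusted p = 0.000589), interferon-stimulated (0.15, adjusted p = 0.00164) and smooth muscle (0.13, adjusted p = 0.00386) genes were higher (adjusted p = 0.684, 0.684 and 0.49 with an estimated correlation). Mitochondrial genome transcripts (−0.13), ribosomal protein genes (−0.03), nuclear oxidative phosphorylation (−0.02) and B cell markers (−0.33) were lower by camera alone, at adjusted p = 5.02e-07, 5.02e-07, 0.0106 and 0.0245 (adjusted p = 0.528, 0.567, 0.847 and 0.684 with an estimated correlation). When adjusted over the list alone none of these 7 lists had a member past the threshold.

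Libraries M10 and M18, labelled male DKO, had Ldlr KO levels of the genes near Ptgir, and the male comparison was therefore repeated without them, a choice made after seeing the data. It then called 32 genes, 18 higher and 14 lower, which kept all 17, and 30 of the 32 lay within 20 Mb of Ptgir. More calls near Ptgir were built into that choice, because M10 and M18 were left out for their levels of those genes. The rise is therefore no independent support. Leaving out M1 gave 11 calls and M18 alone 26. The calls of Gipr (without M1 or M24), Zfp112 (10 of 36 fits), Dhx34 (11) and Zfp61 (12) ended in leave-one-out fits, and a fit of the male groups alone called 2 genes.

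The 3 comparisons shared changes close to Ptgir. Genes near Ptgir called in both kidney and female atria numbered 8, of which 7 had the same sign. All 3 comparisons called 6, of which Sae1, Pnmal2, Ercc2, Dhx34 and Gm45104 had the same sign and Exoc3l2 was higher in kidney (0.43, adjusted p = 0.0328) but lower in atria; for kidney, Ercc2 (−0.70), Dhx34 (1.07), Exoc3l2 and Gm45104 (2.27) were chosen after their values were seen, and the calls of Exoc3l2 and Ercc2 ended in 8 and 11 of 16 leave-one-out fits. Of 1191 kidney calls elsewhere that were tested in atria 643 had the same sign in females and 848 in males, and 0 were called in either by edgeR.

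Females and males were set side by side through separate control libraries. Of the 16 higher female and 14 higher male calls 11 were shared, where independent lists would share 0.0142 (Fisher's exact p = 4.38e-33), and of the 22 and 3 lower calls 3 were shared (0.0042 for independent lists, p = 2.38e-09). None went opposite ways. The shared genes other than Gm11677 lay within 20 Mb of Ptgir, so they are not the independent draws that the Fisher test takes them for. Outside that window the sexes had 2 and 1 higher calls with 1 shared, and 6 and 0 lower calls with 0 shared. Of the 38 female calls 34 had the same sign in males, and all 17 male calls had the same sign in females. Across all genes the fold changes had a Pearson r of 0.158 and a Spearman rho of 0.051 (genes are not independent replicates), and without the genes near Ptgir r was −0.007 and rho 0.031.

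No gene passed the test of whether the genotype difference depended on sex. The 5 genes with the smallest p, given as values, were Has3 (−0.68), which makes hyaluronan, Mtr (0.31), Gbp11 (−1.45), Milr1 (−0.93) and the platelet receptor Gp1ba (−1.43), in female minus male terms, with adjusted p = 0.408 for Has3 and 0.513 for the rest. For Ptgir the interaction was −0.33 (adjusted p = 0.861), and for Nppa −0.01 (adjusted p = 0.986). By edgeR 0 genes passed, 865 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Interferon-stimulated genes were lower as a group (median −0.37, camera adjusted p = 1.69e-12, and adjusted p = 0.299 with an estimated correlation), with 0 of 21 called over all genes. When adjusted over the list alone 8 were lower, among them Stat1 (−0.45), Usp18 (−0.64), Ifit3 (−0.74) and Mx2 (−0.81). Without F7 Ifit3 was at −0.49 and Mx2 at −0.56. Whichever library was left out, Stat1 stayed at −0.32 or below and Usp18 at −0.45 or below. The other lists past camera were nuclear oxidative phosphorylation (0.07, adjusted p = 3.08e-09), heat shock and unfolded protein response (0.14, 0.00109), fatty acid oxidation (0.08, 0.00364), ribosomal proteins (0.02, 0.016), immediate early genes (−0.41, 0.0214; 2 lower when adjusted over the list alone) and neutrophil markers (−1.13, 0.0214). With an estimated correlation these 6 had adjusted p = 0.687, 0.687, 0.718, 0.718, 0.711 and 0.687 in that order.

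Between the sexes, Ldlr KO atria differed in sex-linked genes and in a set of other genes, among them the complement component C7. C7 was lower in females, at 8.89 ± 1.49 CPM against 42.3 ± 6.62 CPM in males (n = 9 each; log2 difference −2.25, SE 0.131, adjusted p = 1.54e-15). The interferon-inducible Ifi205 (−1.96), the calcium-binding Cpne7 (−1.32), Hsd11b1 (−0.77), which regenerates active glucocorticoid, and the enkephalin precursor Penk (−1.56) were also lower in females. Higher in females were X-linked genes known to escape X inactivation, Eif2s3x (0.73), Kdm5c (0.75), Kdm6a (0.83), Ddx3x (0.57) and Pbdc1 (0.60), and the matrix genes Thbs2 (0.56) and Smoc2 (0.60). Ace, which makes angiotensin II, was lower in females (−0.41, adjusted p = 0.016; 40.9 to 75.5 CPM in females and 64.9 to 93.8 CPM in males), as the 1 call among 10 genes of the renin-angiotensin system (1 when adjusted over the list alone; camera adjusted p = 0.0532).

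Of the 65 genes called by edgeR in Ldlr KO atria 31 were higher and 34 lower in females, with 11 on the X and 5 on the Y chromosome. The Wnt inhibitor Sfrp1 (0.30), Gfra1 (0.68), Itga11 (0.63), Cpz (0.82), Rab15 (0.79) and the endothelial Vwf (0.31) were higher, and Smim41 (−1.06), Bmper (−0.62), Inmt (−0.97), Serpina3c (−1.33) and Col6a5 (−2.78) were lower. The calls of Cpz and Col6a5 ended in 9 and 10 of 36 leave-one-out fits, and Col6a5 was at −1.45 without M5. B cell genes were lower in females as a group (median −0.56; camera adjusted p = 0.00103; adjusted p = 0.453 with an estimated correlation), with 0 of 7 called over all genes and 3 when adjusted over the list alone, Ighm (−0.74), Ms4a1 (−1.11, and −0.49 without M5) and Cd79a (−0.77). Interferon-stimulated (0.16) and immediate early (0.33) genes were higher as groups (camera adjusted p = 0.00103 each; adjusted p = 0.57 with an estimated correlation). In all 8 lists passed camera and 0 did so with an estimated correlation. Nppa (0.09, adjusted p = 0.718), Nppb (0.28, adjusted p = 0.893), Npr1 (−0.06), Npr3 (−0.04) and Corin (−0.07) did not pass, and neither did Ptgir (0.39, adjusted p = 0.121), which passed without M25.

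In libraries labelled DKO C7 was again lower in females, at 8.76 ± 1.27 against 37.4 ± 9.97 CPM (log2 difference −2.09, SE 0.131, adjusted p = 1.59e-14), as were Ifi205 (−1.55), Cpne7 (−1.16), Hsd11b1 (−0.65), Serpina3c (−1.63) and Ace (−0.43, adjusted p = 0.00875). Eif2s3x (0.72), Kdm5c (0.84), Kdm6a (0.61), Ddx3x (0.44), Pbdc1 (0.58), Jpx (0.58), Gfra1 (0.53) and Vwf (0.29) were higher in females. Called here were also the growth factor Igf1 (−0.51), Has3 (−0.60), the calcium pump Atp2b2 (−1.14), the lymphoid factor Irf4 (−0.83), Ighg2c (−0.81) and the endothelial selectin Sele (−0.59), all lower in females, and Col5a3 (0.42), Irf2bp2 (0.41) and Tent5b (1.10), higher in females. Whether these differed from Ldlr KO is the interaction above, where no gene passed.

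**Figure D4:**
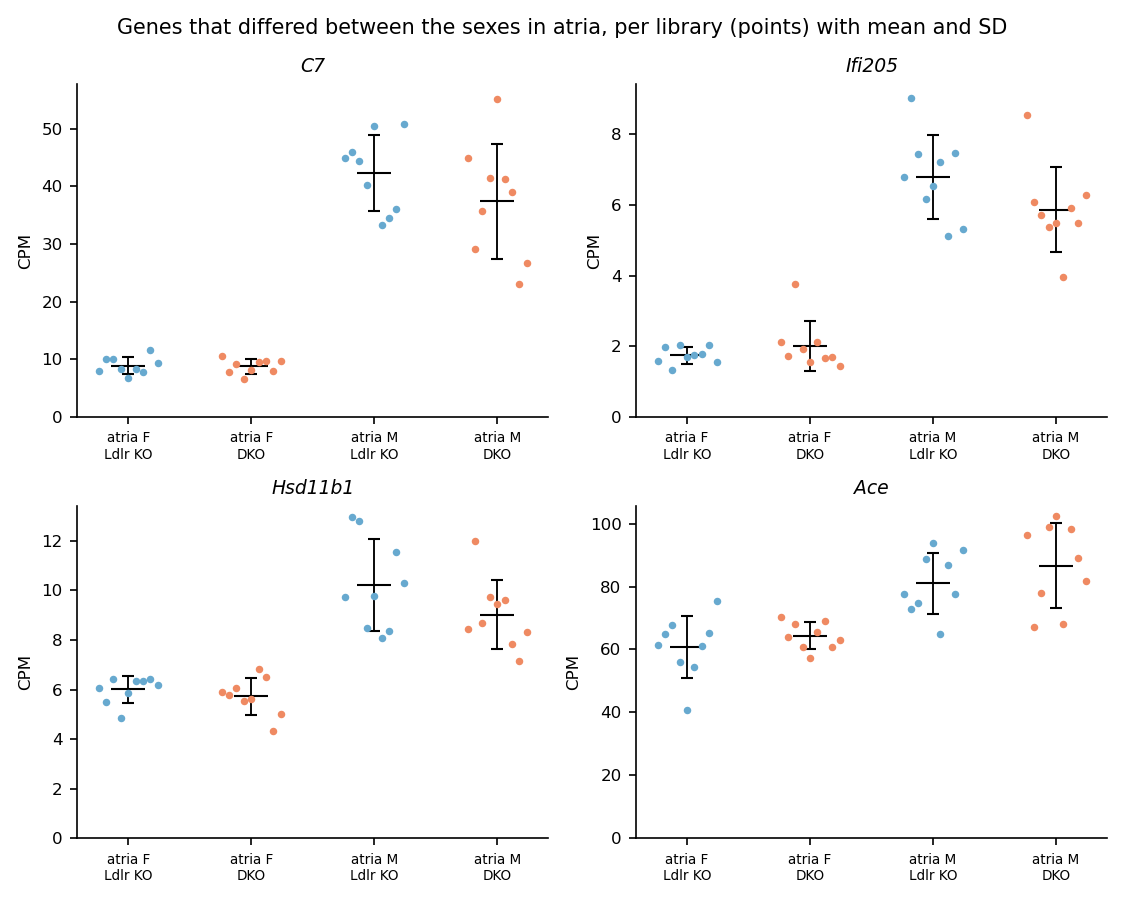
Levels of C7, Ifi205, Hsd11b1 and Ace in CPM (vertical axes, from 0) for each atrial library (points) in the 4 groups (F, females; M, males), with the mean (long bar) and SD (error bars). C7 averaged 8.89 and 8.76 CPM in the female groups and 42.3 and 37.4 CPM in the male groups.

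In labelled DKO atria edgeR called 162 genes, 62 higher and 100 lower in females, with 16 on the X and 5 on the Y chromosome. The atrial cardiomyocyte gene Myl7 rose (0.19, adjusted p = 0.0119) among 2 of 11 called (2 when adjusted over the list alone; camera adjusted p = 0.00528), and the macrophage gene Mrc1 fell (−0.25, adjusted p = 0.0293) as 1 of 10 (2 when adjusted over the list alone; camera adjusted p = 0.00503). Both lists had an adjusted p = 0.874 with an estimated correlation. Hpgds, which makes prostaglandin D, fell (−0.55, adjusted p = 0.0311) as 1 of 19 prostanoid genes (1 when adjusted over the list alone; camera adjusted p = 0.652). Markers of erythroid cells (median −0.68, 0 of 6 called over all genes, 6 when adjusted over the list alone) and B cells (−0.60, 0 of 7 called, 2 when adjusted over the list alone) were lower as groups at camera adjusted p = 0.00673 each. All 8 lists of this contrast that passed camera had an adjusted p = 0.874 with an estimated correlation. Nppa (0.08, adjusted p = 0.449), Nppb (0.11), Npr1 (−0.07), Npr3 (−0.05) and Corin (−0.06) did not pass. The count was 97 without M10 and M18 (87 shared), 84 without F8, 89 without F4, 90 without M6 and 98 without M26, and 314 and 389 by DESeq2 and limma-voom, while the calls of Mrc1 and Hpgds each ended in 7 of 36 leave-one-out fits.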

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

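Of the tests in this part, those on libraries M10 and M18, the one on transcript length and GC content as the whole cause of the kidney pattern, and the kidney tests within each second index and fits on random sets of libraries were chosen only after the result was seen.

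Single libraries stood far from the others of their group for 7 of 76 sets of levels, where chance gives about 1 in 20, or 3.8. Ldlr in the labelled DKO kidney library ST16 was 92.0 CPM, with the next at 59.1 CPM. In the female Ldlr KO atrial library F9, Sae1 was 45.3 CPM (next 40.6) and Ercc2 16.3 CPM (next 20.1). Ercc2 in the labelled DKO female library F10 was 12.6 CPM, in a group that reached only 13.3 CPM. Nppb in the labelled DKO male library M14 was 1038 CPM, with the next at 593.5 CPM. Ifi205 was 3.77 CPM in the labelled DKO female library F6 (next 2.12) and 8.55 CPM in the labelled DKO male library M2 (next 6.28). The log2 fold change of Ighv1-72 was 2.12 in kidney and −1.26 in female atria, a difference of 3.38, and that of Ceacam2 was −4.14 in kidney and 0.92 in male atria, a difference of −5.06. In both cases every labelled DKO library lay above the Ldlr KO mean in one tissue and below it in the other. For kidney Ceacam2 that mean rests on 5 of 8 libraries. Neither gene was called by edgeR in the atrial comparison given. Ceacam2 was low in male atria, at 0.0875 to 0.624 CPM in Ldlr KO and 0.443 to 1.001 CPM in labelled DKO libraries. The difference between tissues was not tested, and these values do not establish opposite changes.

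Random splits of the same libraries bear on each number of called genes. In kidney 3 of 100 splits, the real one included, called at least the real 1433 genes, with 3808 as the highest other. The shares were 2 of 100 for female atria (38 genes, highest other 1260) and 3 of 100 for male atria (17 genes, highest other 34). For females against males they were 1 of 100 in Ldlr KO (65 genes, highest other 1) and 1 of 100 in labelled DKO (162 genes, highest other 16). Each of these 5 shares lies under 0.05. For the genotype counts this argues against chance alone. For females against males a small share was given in advance, because X-linked and Y-linked genes differ between the sexes whatever else does. With only 100 splits and no adjustment over the 5 counts, chance is not excluded. For the interaction the real count is 0, which all 100 splits reach whatever the data (highest other 1272), so the splits decide nothing there. Splits with several times the real count point to a structure among the samples that the labels do not name. In kidney the second index alone did not account for it, since each split with all 4 libraries of the rarer index on one side called 0 genes. The split with 3808 calls had 3 of these 4 libraries on one side and the next, with 2161, had 2.

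The calls in atria clustered around Ptgir on chromosome 7. A gene within 20 Mb was called 145.2 times as often as one elsewhere in females and 619.4 times as often in males. Flanking DNA of another strain, carried along when the targeted allele was made and bred, is a candidate explanation that these values are consistent with, in a test set before the result was seen. In kidney the ratio was 1.43, under the bound of 1.5 set before, which argues against such DNA as the source of most kidney calls but not of those shared with atria, such as Sae1 and Pnmal2. An effect of the altered Ptgir locus on its neighbours was not tested and stays open.

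Libraries M10 and M18, labelled male DKO, sat at Ldlr KO levels of the genes near Ptgir. On a scale from the female Ldlr KO mean (0) to the female labelled DKO mean (1) of 21 such genes they lay at −0.12 and −0.11, the other 7 male labelled DKO libraries between 0.81 and 1.17, and F9, labelled female Ldlr KO, at 0.65. An exchange of labels with male Ldlr KO libraries is argued against, since the highest of those lay at 0.0263, and so is a crossover that left the targeted allele in place, since the 6 genes within 1 Mb of Ptgir put both at 0.0163 or below. Whether they may be animals without the targeted allele cannot be told apart from other origins, because Ptgir itself, at 10.4 and 7.01 CPM, varies too much within the labelled DKO group to decide. No biological explanation was tested.

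Ribosomal protein and mitochondrial transcripts fell together in kidney, with list medians of −0.58 and −0.60. A bias against short transcripts between libraries could not be excluded, as 858 other protein-coding genes of the lengths of the ribosomal list had a median of −0.13, with 88 lower and 2 higher calls, which lies between the bounds set before. With offsets for length and GC content 20 of the 32 ribosomal genes still fell, at a median of −0.35 in place of −0.58. The lengths were those of the longest annotated transcript, which need not be the one expressed. The offsets may therefore fall short, and this test cannot decide whether length and GC content were the whole cause. A batch that shifted all libraries of 1 second index alike could not produce the genotype difference, because the index was balanced over genotype. Within the 12 libraries of 1 index the mean log2 CPM of the ribosomal list differed by −0.53 (95% interval −1.05 to −0.00909). That interval only narrowly excludes 0, and 0 of the 32 genes passed in edgeR with these fewer libraries. The 4 libraries of the other index had a difference of −0.807 (−1.77 to 0.153) and 10 of the 32 genes lower. Both genotypes had the same share of each index, so the index as a covariate could not move the difference and says nothing here. The 12 libraries gave 19 calls in all and the 4 gave 296, and 40 random sets that left out 2 libraries of each genotype gave 3 to 2715, 6 of them at most 19, so the number of calls depended on which libraries were used and not on their number alone. The kidney Ldlr KO libraries are numbered ST1 to ST8 and the labelled DKO libraries ST9 to ST16. Any step of sample handling that followed these numbers, which the labels do not state, could not be told apart from genotype. Library totals also differed with genotype, at 13279792 to 14171655 counts in Ldlr KO and 12747168 to 13318217 in labelled DKO. The 10 genes with the most counts held on average 23.1% of counts in Ldlr KO and 17.9% in labelled DKO. The cause of these differences was not tested. A biological difference by genotype stays open.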

How the results depend on the processing

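Alternatives chosen only after the data were seen are the length and GC offsets, the fits within each second index, without the genes near Ptgir, and without M10 and M18 or F9; the cause was not tested for any change below unless it is given. The kidney count of 1433 became 2254 with limma-voom, 729 with surrogate variables (497 shared), 2228 with length and GC offsets (1044 shared), 19 within the more common second index and 296 within the less common one (fold changes of these with a Pearson r of 0.655), and was 1038 to 2101 under the other alternatives, with 813 to 2603 in leave-one-out fits. The female count of 38 became 3 without the genes near Ptgir, by construction, and was 28 to 57 otherwise, with 27 to 49 in leave-one-out fits. The male count of 17 became 26 with limma-voom, 34 with surrogate variables and 2 in a fit of the male groups alone. It was 32 without M10 and M18, where more calls near Ptgir followed from their choice, and 1 without the genes near Ptgir. It spanned 11 to 26 in leave-one-out fits. The interaction count stayed at 0 under every alternative, leave-one-out fits included. Females against males gave 106 with DESeq2 and 98 with surrogate variables in Ldlr KO, in place of 65 (leave-one-out 48 to 70). In labelled DKO they gave 97 without a filter, 314 with DESeq2, 389 with limma-voom and 97 without M10 and M18, in place of 162 (leave-one-out 84 to 238). The correlation of female and male fold changes, 0.158, was 0.336 over genes with an unadjusted p under 0.05 and −0.00697 without the genes near Ptgir. Lists past camera with the preset correlation numbered 10 in kidney, 7, 7 and 7 in the female, male and interaction contrasts and 8 and 8 between the sexes. With an estimated correlation each of these became 0, and with fry 8 in kidney and 0 in the atrial contrasts. Of the 8, the renin-angiotensin, natriuretic peptide and sex steroid lists (adjusted p = 0.0307, 0.0424 and 0.00689) had not passed camera. Of 1826 alternatives for 200 named gene results, called or not, 1623 kept their direction and side of the threshold. An alternative that gave no adjusted p was counted among these if the direction held. The call was lost in 194 (50 and 46 within the more and less common second index, 36 with surrogate variables, 17 in fits of only the 2 groups compared, 17 without a filter). It was gained in 2 (Ldlr in kidney, 0.61 with limma-voom, and Npr1 in kidney, −0.35 with surrogate variables), and 7 reversed. The reversals, none in a called gene, were Nppa in females (−0.0386 with surrogate variables, −0.0193 without F9), Npr3 in females (0.0479 with surrogate variables), Corin in males (0.00269 with limma-voom), and in females against males of labelled DKO Nppa (−0.00589) and Npr3 (0.151) with surrogate variables and Ptgir (−0.00132 without M10 and M18). Adjacent label numbers did not clearly pair the atrial libraries, though the mean correlation within pairs was 0.0828 in females and 0.112 in males against −0.0104 and −0.0141 otherwise: the correlation of their deviations ran from −0.184 to 0.28 in females and −0.134 to 0.217 in males, over 0.1 in 4 and 5 of 9, and 3 and 2 libraries were closest to their own number. With such numbers as a replicate block 48 female, 14 male and 0 interaction genes were called. With totals of 12747168 to 14171655 counts, kidney genes near 1 CPM rest on few reads.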

Other observations

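The division of kidney genes by transcript length and the comparison of kidney with atria away from Ptgir were chosen after the data were seen, and the tests of gene lists were planned.

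Few members of the following kidney lists were called between labelled DKO and Ldlr KO, and the called ones have been named above. Fibroblast markers had a median log2 fold change of 0.29, with 0 of 9 called by edgeR over all genes and 3 when adjusted over the list alone (camera adjusted p = 0.0673). Markers of the thin limb of the loop of Henle (median 0.24, 0 of 6 called) and of principal cells (0.19, 1 of 10 called, the sodium channel gene Scnn1g) had camera adjusted p = 0.314 and 0.272. Intercalated cells (−0.06, 1 of 10 called), the distal convoluted tubule (−0.04, 0 of 6, with 1 higher and 1 lower when adjusted over the list alone) and erythroid cells (−0.06, 0 of 6) did not pass either, at camera adjusted p = 0.427, 0.915 and 0.83. The response to osmotic stress had 1 of 12 genes called, Slc6a6 (1 when adjusted over the list alone; camera adjusted p = 0.125). The circadian clock, whose phase shifts with the hour of sampling, had 0 of 17 genes called and 0 when adjusted over the list alone (camera adjusted p = 0.83).

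Kidney fold changes were larger for longer transcripts. Among the protein-coding genes divided in 5 groups of increasing length, the shortest (258 to 2047 bases) had a median of −0.08, with 14 higher and 242 lower calls, and the longest (5333 to 123179 bases) a median of 0.18, with 147 higher and 19 lower. The 3 groups between had medians of 0.02, 0.09 and 0.12.

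Across the 13040 genes tested in both tissues and lying away from Ptgir, kidney and male atrial fold changes had a Pearson r of 0.147, and kidney and female atrial fold changes an r of −2.36e-05 (across genes, which are not independent replicates). The difference between these values was not tested against a spread between animals, and the kidney libraries came from males alone.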
